A study of Pinus pinaster with 36 samples.

How the data were processed

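Needles, stem and roots were taken from pools of 12 seedlings, 1 pool per biological replicate, and the total RNA of the 36 samples was sequenced as paired-end reads of 150 bp on an Illumina NovaSeq after TruSeq RNA library preparation, per the labels' protocols. Their extraction text, with the library kit and a RNA integrity number above 7, names root RNA alone, so whether it holds for all 36 samples is not sure. The values analysed were raw counts per transcript identifier as deposited by the authors in a single table. Base calling output was converted with bcl2fastq, per the submitters' processing notes. The aligner, the counter, the transcript assembly and the treatment of reads that match several transcripts were not given in the sources used here. Counts of transcripts with near-identical sequence could be shared between identifiers, and such identifiers could not be recognised here. The labels' treatment text describes a root experiment with other ammonium doses and times. The design was therefore taken from the sample titles, their characteristics and the series design, which name 8 mM ammonium or nitrate, 400 or 720 ppm CO2 and 3 organs. All 36 columns matched a sample by name. The labels call the 3 libraries of a group biological replicates.

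The values were whole numbers, and the library totals differed, as in unscaled counts. Of the 224081 identifiers, 1 had 0 counts in all libraries. Replicates were compared in pairs before they were averaged. A chi-square statistic per degree of freedom was between 9.61 and 56.6 over the pairs, with each count taken as an independent fragment. In estimated independent fragments it was 0.448 to 1.51 for transcripts at 1 to 10 CPM and 5.08 to 59.3 for those of at least 100 CPM. The number of fragments is a low estimate, as given below, and lowers the statistic with it. Values under 1 therefore do not show agreement within sampling noise at 1 to 10 CPM. No pair agreed within sampling noise for transcripts of at least 100 CPM. That cannot tell biological replicates from repeat preparations of a sample, which could exceed the noise too. Each library was counted as a replicate because the labels name biological replicates. No file paired identifiers with names or descriptions, and no reference was used. The keyword lists of genes drawn up for the tissue could therefore not be matched to any transcript and were not run.

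The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each organ the 12 libraries were fitted together with a mean per group (8 residual degrees of freedom). Low counts were removed with edgeR's filterByExpr, which uses a minimum count of 10, and libraries were scaled by TMM. Contrasts were tested with edgeR's robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the transcripts tested and calls at an adjusted p under 0.05 without a fold limit. The 5 contrasts were CO2 at 720 against 400 ppm under each nitrogen form, ammonium against nitrate at each CO2 level, and the difference of the CO2 effects (ammonium minus nitrate). Contrasts between organs, and F-tests of differences between organs in the CO2 and nitrogen responses, used all 36 libraries and 12 groups. CPM values are scaled by the TMM library size, and CPM sums over transcript sets by the library total. Standard errors come from the fitted change and its F statistic and are left out for groups at 0 counts. A group at 0 counts was set to 3 counts over the group for ratios. Counting intervals are exact binomial intervals at 95%, and intervals and limits cover counting error only. They take each count as an independent fragment, which the excess of even values speaks against.

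Organ-enriched lists hold transcripts with a log2 fold change over 3 and an adjusted p under 0.05 against both other organs. They were tested with camera on voom values, with a preset correlation of 0.01 and with an estimated one, adjusted over 45 tests. Library measures were compared by two-sided exact permutation tests of 6 against 6 libraries, over 24 tests. A comparison of 3 against 3 libraries by permutation cannot go below p = 0.1, so none was made for library measures. Overlaps of calls are given beside the number that independent lists would share. Comparisons within an organ use the same estimate of spread for a transcript, so their lists are not fully independent.

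The groups, tests and most alternatives were set before the data were examined. So was the rule for named transcripts: for each comparison, the 2 risen and the 2 fallen with the largest fold change among those called, with a mean of at least 5 CPM over the libraries of the fit and, except for the interaction and the organ contrasts, without overlap of the groups compared. The alternatives were DESeq2's size factors in place of TMM, no low-count filter, a fold change over 2, an adjusted p under 0.01 for the tests between organs, the replicate number (or the pool of seedlings) as a block, the DESeq2 test and the removal of each library in turn (each replicate number in turn between organs). Added after the data were seen were the removal of the low-complexity libraries, the removal of root-restricted transcripts, limma-voom with library weights and the limit of 3 independent fragments. Without the low-complexity libraries, needles under nitrate at 400 ppm and stem under ammonium at 400 ppm each held 1 library, which was assumed to vary like the other groups of the fit.

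The labels number the replicates 1 to 3 in every group without saying that a number marks a shared pool or day. Deviations of same-numbered libraries from their group means were therefore correlated. Among the comparisons within organs, every correlation was over 0.1 only for CO2 under nitrate in roots (0.269, 0.167 and 0.273), where the numbers were taken to pair the libraries. Between organs the pairing comes from the series design, in which the 3 organs were taken from each pool, and every correlation was over 0.1 in 7 of 12 checks.

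The fit was tested on simulated counts drawn with the means, library sizes and dispersions of the real libraries, with 50 transcripts at each fold changed between the nitrate groups at 400 and 720 ppm. In needles, 50, 74, 98 and 100% of the changes of 2, 4, 8 and 16-fold were recovered over 109472 transcripts. In stem 32, 60, 88 and 88% were recovered over 127592, and in roots 54, 92, 94 and 96% over 146864. False calls numbered 8, 9 and 16, and the unchanged ammonium comparison gave 0, 0 and 1. The changed transcripts were chosen among those with a mean of at least 1 CPM, so recovery below that was not tested. The root transcripts called for CO2 under nitrate had median levels of 0.444 CPM (fallen) and 0.657 CPM (risen). Each transcript had 1 dispersion for all libraries, so low-complexity libraries and the excess of even values were not simulated.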

Results

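RNA sequencing measured transcript abundance in needles, stem and roots of maritime pine (Pinus pinaster), a Mediterranean conifer. Seedlings aged 2 months had received 40 mL of either ammonium chloride or potassium nitrate, at 8 mM, each week for 1 month, in air with 400 or 720 ppm CO2. The 36 libraries formed 12 groups of 3 biological replicates, 4 groups per organ. Each biological replicate was a pool of 12 seedlings, from which the 3 organs were taken. The deposited table held raw counts for 224081 transcript identifiers. It pairs none of them with a gene name, so transcripts are given by identifier and no function is attached to them. Total counts per library ran from 73414247 to 134836160 in needles, from 76082457 to 111368507 in stem and from 76221102 to 120587917 in roots. Levels are given as CPM, counts scaled to a common library total.

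Libraries of similar depth differed in complexity. The share of identifiers at 0 counts ran from 28.6 to 58.5% in needles, 22.9 to 57.9% in stem and 11.1 to 29.8% in roots. Even values made up 52.5 to 75.4% of the counts above 20. In 7 libraries, which were also the 7 with the most identifiers at 0, the even share was over 65%: ammonium 400 ppm replicate 2, ammonium 720 ppm replicate 3 and nitrate 400 ppm replicates 1 and 2 of the needles, and ammonium 400 ppm replicates 1 and 2 and nitrate 720 ppm replicate 1 of the stem. They are called low-complexity libraries here, and no root library was among them. Among transcripts near 1 CPM in the other libraries of the organ, the share at 0 counts was that of 1.71 to 8.97 independent fragments per 1 CPM, a low estimate, since transcripts absent for other reasons enter it. By it, 3 independent fragments over a group correspond to 0.128 to 0.278 CPM, so group means below that, and ratios taken against them, are uncertain beyond the intervals given.

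**Figure D1:**
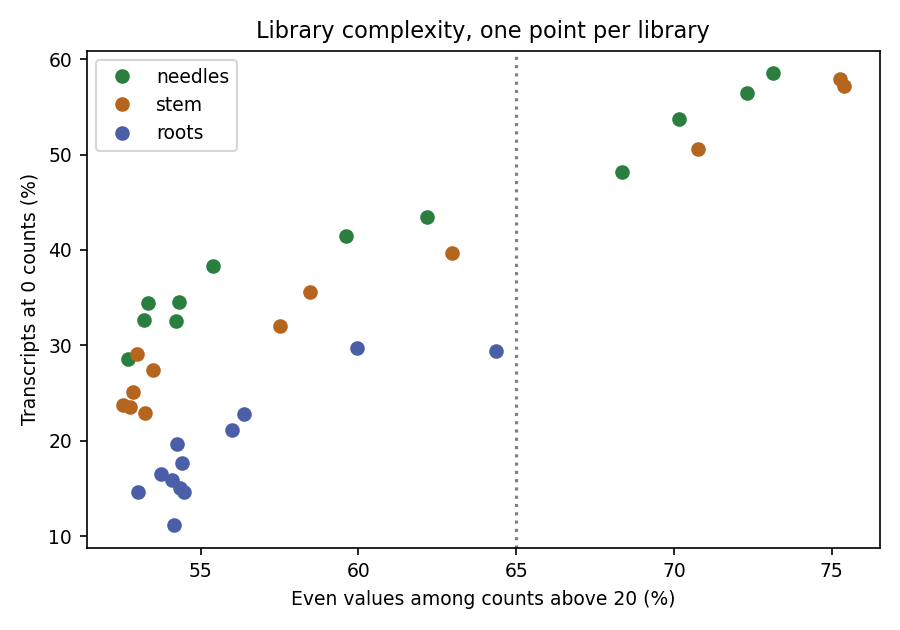
Share of identifiers at 0 counts (vertical axis, %) against the share of even values among counts above 20 (horizontal axis, %), 1 point per library, coloured by organ. The dotted line marks 65%, and the 7 libraries to its right are 4 needle and 3 stem libraries.

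The organs differed widely in transcript abundance. Transcripts over 8-fold higher in needles than in both other organs numbered 4913 and took 17.1 ± 0.797% of needle counts (SD, n = 12), against 2.04 ± 0.517% in stem and 0.176 ± 0.0175% in roots. The same rule gave 22689 root-enriched transcripts, with 5.15 ± 0.972% of root counts against 0.071 ± 0.00496% in needles and 0.181 ± 0.0256% in stem. It gave 692 stem-enriched transcripts with 0.192 ± 0.0182% of stem counts. These lists were chosen on the same libraries, so their levels are not independent evidence of organ differences. Of 186020 transcripts tested over all 36 libraries with edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 31863 were higher and 43495 lower in needles than in stem, and 28414 and 26713 without replicate 3 of every group. Against roots, 32326 were higher and 70782 lower in needles. Between stem and roots, 25103 were higher in stem and 48343 in roots.

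Nitrogen form and CO2 were then compared within each organ, in a fit of its 12 libraries. Ammonium was given as the chloride and nitrate as the potassium salt, so the nitrogen comparisons cannot tell nitrogen form from these ions. The sample titles name no growth chamber or tray. Whether these differed between the groups was not known, so the CO2 comparisons cannot tell CO2 from such a difference. The question was which transcripts respond to ammonium against nitrate, to elevated CO2, and to their combination. Most of the calls lay in the nitrogen comparisons of the roots. With edgeR's quasi-likelihood test the responses themselves differed between organs for 1374 transcripts in the case of nitrogen and 130 in the case of CO2. Without replicate 1 of every group they were 597 and 38, and without replicate 2 they were 221 and 13. The CO2 count was 75 with DESeq2's size factors, 75 without the low-complexity libraries and 283 with the seedling pool as a block. Other splits of the same libraries, given below, did not exclude chance for it.

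**Figure D2:**
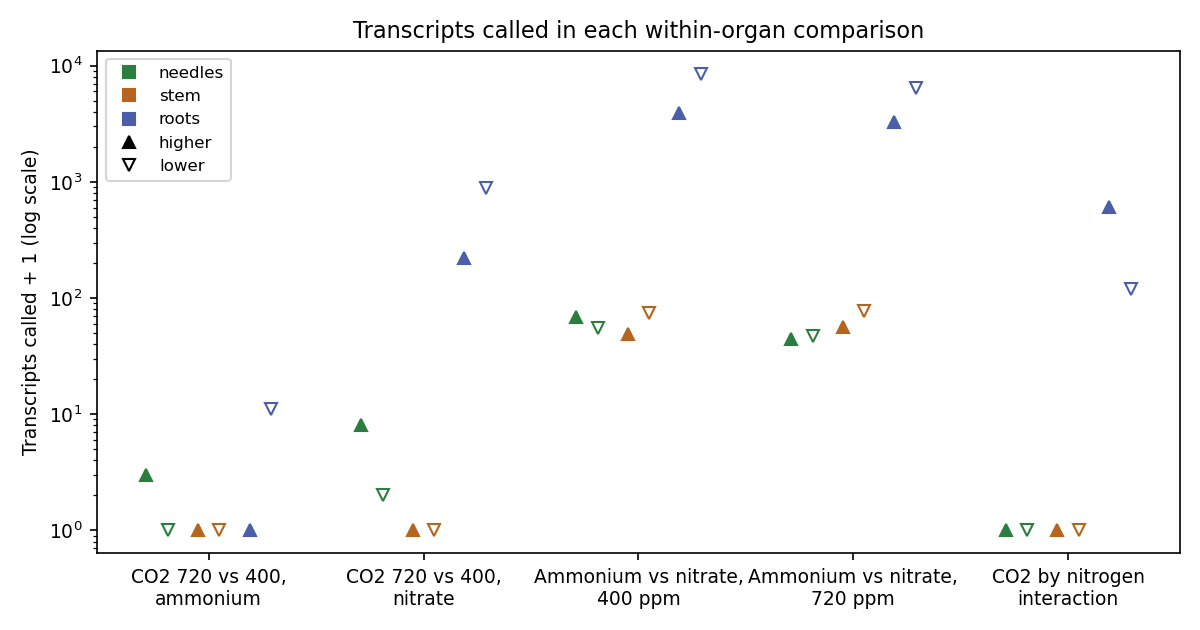
Number of transcripts called plus 1 (vertical axis, log scale) in the 5 within-organ comparisons, by organ (colour) and direction (filled upward triangles higher, open downward triangles lower). The root counts for ammonium against nitrate, 3909 higher and 8547 lower at 400 ppm and 3260 higher and 6393 lower at 720 ppm, lie above all others.

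In roots, ammonium and nitrate differed at both CO2 levels. At 400 ppm, 3909 transcripts were higher and 8547 lower with ammonium than with nitrate, of 156123 tested. PpCO2_22062 was at 8.98 ± 3.29 CPM with ammonium and 0.244 ± 0.152 CPM with nitrate (SD, n = 3), a log2 fold change of 5.18 (SE 0.381, edgeR adjusted p = 1.21e-05). PpCO2_137599 was at 24.1 ± 10.6 against 0.0984 ± 0.0895 CPM, a log2 fold change of 7.93 (SE 1.44, edgeR adjusted p = 0.0106). PpCO2_20585 fell from 18 ± 2.14 CPM with nitrate to 0.0362 ± 0.0327 CPM with ammonium, 9 counts over 3 libraries, and its log2 fold change was -8.89 (SE 0.584, edgeR adjusted p = 1.02e-05). PpCO2_113865 fell from 11.9 ± 6.96 to 0.0167 ± 0.029 CPM, 4 counts, with a log2 fold change of -9.4 (SE 1.32, edgeR adjusted p = 0.00295). The median log2 ratio of the fallen transcripts was -1.47, with 1628 of them at 0 counts in a group and set to the limit of 3 counts, and that of the risen transcripts was 0.94, with 114 at that limit. The count of 12456 calls was 7094 and 8140 without ammonium 400 ppm replicates 1 and 2, 7352, 7465 and 6268 without nitrate 400 ppm replicates 1, 2 and 3, and 7099 with a fold change over 2 required. DESeq2 called 20638. The call of PpCO2_137599 was lost without nitrate 400 ppm replicate 2 (adjusted p = 0.0582) or 3 (0.0547) and with limma-voom (0.264; alternatives up to 0.264), and that of PpCO2_113865 with limma-voom (0.359, the highest of its alternatives).

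At 720 ppm, 3260 root transcripts were higher and 6393 lower with ammonium. PpCO2_28807 was at 11.1 ± 0.24 CPM with nitrate and 0.0166 ± 0.0288 CPM with ammonium, 4 counts, a log2 fold change of -9.49 (SE 0.592, edgeR adjusted p = 3.4e-06). PpCO2_20582 fell from 16.9 ± 1.71 to 0.0412 ± 0.0513 CPM, with a log2 fold change of -8.84 (SE 0.465, edgeR adjusted p = 7.71e-07). PpCO2_162324 was at 8.02 ± 0.0656 CPM with ammonium and 0.0148 ± 0.0256 CPM with nitrate, 4 counts, a log2 fold change of 8.98 (SE 0.451, edgeR adjusted p = 1.9e-07). PpCO2_153738 was at 4.7 ± 0.405 CPM with ammonium, and its 2 counts over the nitrate libraries gave a ratio of 657 with a 95% counting interval of 182 to 5430 (edgeR adjusted p = 1.69e-08). At 400 ppm PpCO2_162324 was at 8.75 ± 0.37 CPM with ammonium and 7.46 ± 2.19 CPM with nitrate. PpCO2_153738 was at 4.17 ± 0.523 CPM with ammonium there and higher, at 12.7 ± 1.73 CPM, with nitrate. Among the root groups, both were thus low in nitrate roots at 720 ppm alone. All 4 named transcripts kept their calls at 720 ppm under every alternative run for them. The count of 9653 calls was 5545, 5848 and 6213 without nitrate 720 ppm replicates 1, 2 and 3, 6425 with a fold change over 2 required and 6066 without root-restricted transcripts, which are defined with the CO2 comparisons. DESeq2 called 16252 and limma-voom 14854.

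The root responses to nitrogen at the 2 CO2 levels, which share no library, had 1296 risen and 4142 fallen transcripts in common, where independent lists would share 81.6 and 350. The log2 fold changes correlated across transcripts with r = 0.459, where transcripts are not independent replicates. Ammonium roots had more of their counts in the 50 most abundant transcripts, 6.12 ± 0.311% against 5.29 ± 0.183% with nitrate (SD, n = 6). All 6 ammonium libraries lay above all 6 nitrate libraries (two-sided exact permutation p = 0.00216, the smallest that 924 permutations allow, 0.0259 after Benjamini-Hochberg adjustment over 24 tests). Neighbouring identifier numbers were often called together, for 45% of the transcripts lower with ammonium at 400 ppm and 50.7% at 720 ppm, against 10.6 and 8.02% for numbers placed at random. The calls count identifiers, and how many genes these stand for was not known.

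In needles, ammonium raised 67 and lowered 54 of 117123 transcripts at 400 ppm. PpCO2_84553 was at 9.26 ± 4.22 CPM with ammonium and 1.18 ± 0.263 CPM with nitrate (SD, n = 3), a log2 fold change of 2.97 (SE 0.385, edgeR adjusted p = 0.00685). PpCO2_3478 was at 8.79 ± 1.64 against 2.31 ± 0.317 CPM, a log2 fold change of 1.93 (SE 0.231, edgeR adjusted p = 0.00313). PpCO2_178487 fell from 16.8 ± 13.1 to 0.594 ± 0.146 CPM and PpCO2_178484 from 15.6 ± 9.61 to 0.61 ± 0.333 CPM, with log2 fold changes of -4.81 (SE 0.559) and -4.66 (SE 0.616) and edgeR adjusted p of 0.00655 and 0.0184. The count of 121 calls was 43 and 47 without ammonium 400 ppm replicates 1 and 2, 61 and 78 without nitrate 400 ppm replicates 1 and 2, 250 with no low-count filter, 1158 with DESeq2 and 41 with limma-voom. More transcripts were then lower than higher without ammonium 400 ppm replicates 1 (18 higher, 25 lower) and 2 (18 and 29), without nitrate 400 ppm replicates 1 (25 and 36) and 2 (34 and 44), without the low-complexity libraries (44 and 53, from 2 ammonium libraries and 1 nitrate library) and with limma-voom (12 and 29). The call of PpCO2_84553 was lost without nitrate 400 ppm replicate 1 (adjusted p = 0.0883) or 2 (0.0615), that of PpCO2_178487 without any of ammonium 400 ppm replicates 1 (0.125), 2 (0.137) and 3 (0.0514), and that of PpCO2_178484 without ammonium 400 ppm replicate 1 (0.202), 2 (0.124) or 3 (0.0661) or nitrate 400 ppm replicate 1 (0.086). PpCO2_3478 lost its call without the low-complexity libraries (0.251, with a log2 fold change of 1.57), a fit with 1 nitrate library at 400 ppm, assumed to vary like the other groups. Over all alternatives the adjusted p reached 0.727 for PpCO2_84553, 0.251 for PpCO2_3478, 0.759 for PpCO2_178487 and 0.291 for PpCO2_178484.

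At 720 ppm, ammonium raised 43 and lowered 46 needle transcripts. PpCO2_50685 was at 29 ± 4.05 CPM with ammonium and 8.4 ± 3.54 CPM with nitrate (SD, n = 3), and PpCO2_166051 at 18.6 ± 4.6 and 5.45 ± 1.81 CPM. Their log2 fold changes were 1.79 (SE 0.288) and 1.77 (SE 0.242), with edgeR adjusted p of 0.0452 and 0.0112. PpCO2_178483 fell from 13.7 ± 2.11 to 0.379 ± 0.299 CPM and PpCO2_178484 from 6.49 ± 0.952 to 0.231 ± 0.18 CPM, with log2 fold changes of -5.08 (SE 0.588) and -4.72 (SE 0.651) and edgeR adjusted p of 0.0116 and 0.0268. The 2 CO2 levels had 17 risen and 33 fallen transcripts in common, where independent lists would share 0.0246 and 0.0212. Over all transcripts tested, the log2 fold changes at the 2 levels hardly correlated (r = 0.0508). The count of 89 calls was 50 and 59 without ammonium 720 ppm replicates 2 and 3, 46, 44 and 50 without nitrate 720 ppm replicates 1, 2 and 3, 174 without the low-complexity libraries, 182 with no low-count filter, 550 with DESeq2 and 551 with limma-voom. More transcripts were then higher than lower with DESeq2 (328 and 222), limma-voom (360 and 191), no low-count filter (109 and 73), the replicate number as a block (59 and 51), without the low-complexity libraries (97 and 77), without ammonium 720 ppm replicates 1 (48 and 32) and 3 (34 and 25) and without nitrate 720 ppm replicate 1 (25 and 21). Without single libraries PpCO2_166051 lost its call for nitrate 720 ppm replicate 1 (adjusted p = 0.0809), PpCO2_50685 for ammonium 720 ppm replicates 1, 2 and 3 (0.191, 0.253 and 0.146) and nitrate 720 ppm replicates 1 (0.302) and 3 (0.0852), PpCO2_178483 for ammonium 720 ppm replicates 1 (0.147) and 2 (0.0606) and nitrate 720 ppm replicates 1, 2 and 3 (0.0809, 0.0863 and 0.0852), and PpCO2_178484 for all 6 libraries compared (0.0678 to 0.196). Over all alternatives the adjusted p reached 0.338 for PpCO2_50685 and stayed within the values given for PpCO2_166051, PpCO2_178483 and PpCO2_178484.

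In stem, ammonium raised 48 and lowered 73 of 137689 transcripts at 400 ppm. PpCO2_76727 was at 142.2 ± 35 CPM with ammonium and 23.1 ± 2.17 CPM with nitrate (SD, n = 3), a log2 fold change of 2.62 (SE 0.179, edgeR adjusted p = 1.72e-05) that passed the threshold under every alternative. PpCO2_89503 was at 47.5 ± 16.6 and 7.89 ± 0.0828 CPM, a log2 fold change of 2.59 (SE 0.379, edgeR adjusted p = 0.0339). PpCO2_20584 fell from 16.4 ± 5.47 to 0.0543 ± 0.0485 CPM, 14 counts, and PpCO2_20586 from 12.3 ± 3.18 to 0.0427 ± 0.0471 CPM, 11 counts. Their log2 fold changes were -8.31 (SE 0.544) and -8.24 (SE 0.542), with edgeR adjusted p of 2.56e-05 and 2.03e-05, and only limma-voom lost their calls (adjusted p = 0.958 and 0.784, the highest of their alternatives). The count of 121 calls was 80 and 558 without ammonium 400 ppm replicates 1 and 3, 64 and 68 without nitrate 400 ppm replicates 2 and 3, 65 without the low-complexity libraries (1 ammonium library at 400 ppm, assumed to vary like the other groups), 538 with DESeq2 and 49 with limma-voom, 31 of them higher and 18 lower. PpCO2_89503 lost its call without ammonium 400 ppm replicates 1 (adjusted p = 0.153) or 2 (0.0835), without nitrate 400 ppm replicates 1 (0.286), 2 (0.335) or 3 (0.333), and in other alternatives, up to 0.335.

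At 720 ppm, ammonium raised 55 and lowered 76 stem transcripts. PpCO2_89503 was at 37 ± 9.73 CPM with ammonium and 6.86 ± 3.46 CPM with nitrate (SD, n = 3), a log2 fold change of 2.43 (SE 0.377, edgeR adjusted p = 0.0458), and PpCO2_76730 at 7.86 ± 3.16 and 1.73 ± 0.923 CPM, a log2 fold change of 2.18 (SE 0.373, edgeR adjusted p = 0.0459). PpCO2_139065 had 0 counts in the ammonium libraries against 10.2 ± 2.09 CPM with nitrate (edgeR adjusted p = 0.0256), and 3 independent fragments there correspond to 0.178 CPM. PpCO2_178484 fell from 10.1 ± 2.22 to 0.1 ± 0.0334 CPM, 25 counts, a log2 fold change of -6.67 (SE 0.743, edgeR adjusted p = 0.00529). The 2 CO2 levels had 34 risen and 52 fallen transcripts in common, where independent lists would share 0.0192 and 0.0403. Over all transcripts tested, the log2 fold changes at the 2 levels hardly correlated (r = 0.0754). The count of 131 calls was 61, 50 and 49 without ammonium 720 ppm replicates 1, 2 and 3, 61, 60 and 53 without nitrate 720 ppm replicates 1, 2 and 3, 820 with DESeq2 and 340 with limma-voom. More were then higher than lower without ammonium 720 ppm replicate 1 (33 and 28) and with limma-voom (173 and 167). The calls of the 4 transcripts did not survive the loss of single libraries: PpCO2_139065 lost its call without any of the 6 (adjusted p from 0.132 to 0.199), PpCO2_89503 without ammonium 720 ppm replicates 1, 2 and 3 (0.248, 0.289 and 0.125) or nitrate 720 ppm replicates 2 and 3 (0.114 and 0.312), PpCO2_76730 without ammonium 720 ppm replicates 2 and 3 (0.2 and 0.207) or nitrate 720 ppm replicates 1 and 3 (0.0816 and 0.251), and PpCO2_178484 without ammonium 720 ppm replicates 1, 2 and 3 (0.0874, 0.0931 and 0.0924). Over all alternatives the adjusted p reached 0.59 for PpCO2_139065 and 0.209 for PpCO2_178484.

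A small set of transcripts differed between ammonium and nitrate in every organ at both CO2 levels. Of 104074 transcripts tested in all 3 organs, 25 were lower and 4 higher with ammonium in all 6 comparisons, where independent lists would give 1.19e-11 and 3.27e-12. The 25 lay in 11 runs of consecutive identifier numbers and included PpCO2_178484, PpCO2_20584 and PpCO2_20585 above. Their median log2 ratio of ammonium to nitrate was -3.28 in needles, -5.63 in stem and -5.56 in roots at 400 ppm, and -3.24, -3.81 and -4.92 at 720 ppm. The 4 higher transcripts had medians from 0.84 in stem at 400 ppm to 1.38 in needles at 400 ppm. Both sets were taken from the main fits alone and were not counted under the alternatives. Membership can depend on single libraries: PpCO2_178484 lost its needle call at 720 ppm without any single library of that comparison. The organs of a group came from the same seedling pools, so overlaps between organs are descriptive. Of the 73 stem transcripts lower with ammonium at 400 ppm, all tested in roots, 69 were also lower in roots, where 2.91 would be shared by independent lists, and of the 48 higher, 38 were shared against 1.37. Needles and roots shared 42 of 54 lower transcripts at 400 ppm against 2.23.

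**Figure D3:**
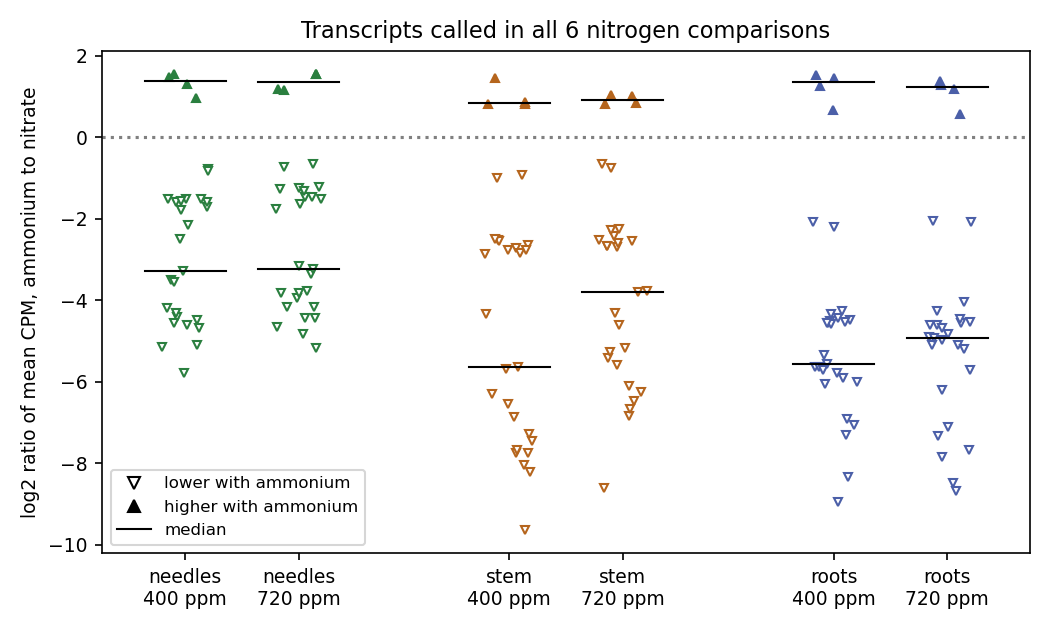
Log2 ratio of mean CPM, ammonium to nitrate (vertical axis), for the 25 transcripts lower (open triangles) and 4 higher (filled triangles) with ammonium in all 6 nitrogen comparisons, by organ and CO2 level. Black lines are medians over transcripts, from -3.24 to -5.63 for the lower set; a group at 0 counts was set to 3 counts over the group, which concerned 1 transcript in stem at 400 ppm.

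The organ-enriched lists were tested in each comparison, those of the other organs as markers of tissue carried over. Camera tests of the 3 organ-enriched lists in the 15 comparisons passed an adjusted p of 0.05 in 8 of 45 cases with a preset correlation and in none with an estimated one, for lists at a log2 fold change over 3. In roots, the root-enriched list was lower with ammonium: of 22601 members 375 rose and 2529 fell at 400 ppm (551 and 3345 adjusted over the list alone), with a median log2 fold change of -0.89 (camera adjusted p = 2.93e-09, and adjusted p = 0.715 with an estimated correlation). At 720 ppm, 590 rose and 2140 fell (749 and 2886 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 2.31e-10, and adjusted p = 0.715 with an estimated correlation). Of all root transcripts called lower with ammonium, 26.9% at 400 ppm and 31.8% at 720 ppm were root-restricted, as defined below. Of those called higher 7.34 and 33.2% were, and of those tested 10.9%. The needle-enriched list in stem, 2276 members, had a median of -0.85 at 720 against 400 ppm CO2 under nitrate (camera adjusted p = 1.55e-28, and adjusted p = 0.752 with an estimated correlation), with 0 members called over all transcripts and 133 lower adjusted over the list alone. Its share of the counts was 2.57, 2.06 and 3.15% in the 3 nitrate stem libraries at 400 ppm and 1.63, 1.43 and 1.71% in those at 720 ppm. It also passed with the preset correlation for ammonium against nitrate at 400 ppm (median -0.44, adjusted p = 0.000128) and at 720 ppm (0.41, 0.00499), for the interaction (0.86, 4.89e-07, where the median of all transcripts was 0.15) and for CO2 under ammonium (0.0195). In the last case the median was -0.04 and the mean 0.23. With an estimated correlation all of these had an adjusted p = 0.989, and no more than 1 member was called in any of them. The root-enriched list in needles had a median of 0.42 for CO2 under nitrate (camera adjusted p = 0.00223, and adjusted p = 0.989 with an estimated correlation), with 0 of 1392 members called. The stem-enriched list at that limit passed in no comparison, and its lowest adjusted p was 0.183. For ammonium against nitrate in roots its 160 members had a median of -0.05 at 400 ppm, with 1 risen and 6 fallen, and -0.08 at 720 ppm, with 2 risen and 7 fallen. With the limit at a log2 fold change over 1, its 2966 members had the other direction there and passed with both correlations. At 400 ppm their median for ammonium against nitrate was 0.33, with 270 risen and 46 fallen (323 and 54 adjusted over the list alone; camera adjusted p = 1.77e-08, and adjusted p = 0.0392 with an estimated correlation). At 720 ppm the median was 0.28, with 161 risen and 46 fallen (189 and 51; camera adjusted p = 1.78e-06, and adjusted p = 0.0415 with an estimated correlation).

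Few needle transcripts were called for elevated CO2 in the main fit, though the count depended on the test. Under ammonium, 2 transcripts were higher and 0 lower at 720 than at 400 ppm by edgeR's quasi-likelihood test, with 8002 of 117123 at an unadjusted p under 0.05. PpCO2_158347 rose from 15 ± 1.59 to 29.6 ± 2.96 CPM and PpCO2_17863 from 33.8 ± 1.3 to 61.9 ± 6.06 CPM (SD, n = 3), with log2 fold changes of 0.98 (SE 0.117) and 0.87 (SE 0.106) and an edgeR adjusted p of 0.0319 for each. DESeq2 called 1042 transcripts, limma-voom 146, the fit with no low-count filter 168 and the fit without low-complexity libraries 20. The count was 0 without ammonium 400 ppm replicate 1 or 3 or ammonium 720 ppm replicate 1 or 2, 1 without ammonium 400 ppm replicate 2 and 4 without ammonium 720 ppm replicate 3. Both named transcripts lost their calls in all of these but the last (adjusted p up to 0.292). At 720 ppm the 50 most abundant transcripts took 14.1 ± 0.875% of needle counts, against 11.8 ± 0.907% at 400 ppm (SD, n = 6). All 6 libraries at 720 ppm lay above all 6 at 400 ppm (two-sided exact permutation p = 0.00216, the smallest possible, 0.0259 after Benjamini-Hochberg adjustment over 24 tests).

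Under nitrate, 7 needle transcripts were higher and 1 lower at 720 ppm. PpCO2_86387 rose from 13.2 ± 2.59 to 37.1 ± 5.01 CPM and PpCO2_154780 from 18 ± 0.415 to 47.4 ± 8.09 CPM (SD, n = 3), with log2 fold changes of 1.5 (SE 0.194) and 1.4 (SE 0.149) and edgeR adjusted p of 0.0362 and 0.0127. PpCO2_91546 fell from 44.2 ± 7.51 to 22.8 ± 0.907 CPM, with a log2 fold change of -0.95 (SE 0.124, edgeR adjusted p = 0.0362). Its levels under ammonium were 42.6 ± 4.34 and 23.7 ± 1.79 CPM, without a call there. DESeq2's size factors gave 2 higher and 1 lower, the test of DESeq2 950 calls, limma-voom 188, no low-count filter 329 and the fit without low-complexity libraries, with 1 nitrate library at 400 ppm assumed to vary like the other groups, 35. The count of 8 was 64, 0 and 51 without nitrate 400 ppm replicates 1, 2 and 3, and 0, 4 and 89 without nitrate 720 ppm replicates 1, 2 and 3. PpCO2_86387 lost its call without nitrate 400 ppm replicates 1 (adjusted p = 0.0508) or 2 (0.138) or nitrate 720 ppm replicates 1 (0.149) or 2 (0.16), PpCO2_154780 without nitrate 400 ppm replicate 2 (0.0507) or nitrate 720 ppm replicate 1 (0.0505), and PpCO2_91546 without nitrate 400 ppm replicate 2 (0.0884) or nitrate 720 ppm replicates 1 (0.135) or 2 (0.122). Without the low-complexity libraries the adjusted p was 0.203 for PpCO2_86387 and 0.104 for PpCO2_154780, the highest of their alternatives.

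In stem, edgeR's quasi-likelihood test called 0 transcripts for CO2 under ammonium, with 7931 of 137689 at an unadjusted p under 0.05, and 0 under nitrate, with 3564. DESeq2 called 494 and 189, and limma-voom with library weights called 3 under nitrate. Under ammonium the count was 298 without ammonium 400 ppm replicate 3 and 5 without ammonium 720 ppm replicate 2, 12 with no low-count filter, 8 without the low-complexity libraries (1 library at 400 ppm, assumed to vary like the other groups) and 2, both lower, with DESeq2's size factors. Under nitrate it was 3 without nitrate 720 ppm replicate 2. Replicate 3 is the only library of the ammonium 400 ppm stem group that is not of low complexity.

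In roots under ammonium, 10 transcripts were lower and 0 higher at 720 ppm by edgeR's quasi-likelihood test, with 14116 of 156123 at an unadjusted p under 0.05. PpCO2_125992 fell from 34.8 ± 3.35 to 17.2 ± 1.42 CPM and PpCO2_29164 from 131 ± 18.6 to 65.2 ± 3.45 CPM (SD, n = 3), with log2 fold changes of -1.01 (SE 0.12) and -1.01 (SE 0.123) and an edgeR adjusted p of 0.0407 for each. The median log2 ratio of the 10 was -0.85. DESeq2 called 529 higher and 621 lower, limma-voom 13 and 62, and the fit with no low-count filter 12 and 24. The count was 0 without ammonium 400 ppm replicate 1 or 3 or ammonium 720 ppm replicate 2 or 3, 4, all lower, without ammonium 400 ppm replicate 2, and 2 higher and 2 lower without ammonium 720 ppm replicate 1. Both named transcripts lost their calls in 5 of these 6 fits, all but that without ammonium 400 ppm replicate 2, with an adjusted p up to 0.156 for PpCO2_125992 and 0.148 for PpCO2_29164.

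In roots under nitrate, 876 transcripts fell and 221 rose at 720 ppm, of 156123 tested, and 466 of the fallen ones had 0 counts in all 3 libraries at 720 ppm. PpCO2_25229 fell from 43 ± 15.1 to 0.0526 ± 0.0209 CPM, 14 counts (SD, n = 3), with a log2 fold change of -9.68 (SE 0.356, edgeR adjusted p = 1.43e-07), and its level under ammonium was 10.2 ± 1.37 and 8.7 ± 1.47 CPM. PpCO2_153738 fell from 12.7 ± 1.73 CPM to 2 counts over 3 libraries, a ratio of 1750 with a 95% counting interval of 484 to 14500 (edgeR adjusted p = 2.78e-08). PpCO2_54562 rose from 1.17 ± 0.17 to 3.96 ± 1.44 CPM and PpCO2_136231 from 1.84 ± 0.448 to 4.18 ± 0.858 CPM, with log2 fold changes of 1.76 (SE 0.278) and 1.19 (SE 0.229) and edgeR adjusted p of 0.00851 and 0.0298. With these at 3 counts over the group, the median log2 ratio of the fallen transcripts was -5.83. For the risen ones it was 6.28, with 73 at that limit. With group means set to no less than 3 independent fragments the medians were -1.68 and 2.66. The count of 1097 was 674 without nitrate 400 ppm replicate 3 and 2831 with DESeq2, 1785 fallen and 1046 risen. The number risen depended on single libraries: it was 70, 85 and 48 without nitrate 400 ppm replicates 1, 2 and 3 and 121, 139 and 127 without nitrate 720 ppm replicates 1, 2 and 3. The number fallen was 709, 707 and 626, and 651, 655 and 634. PpCO2_54562 lost its call without nitrate 400 ppm replicates 1 (adjusted p = 0.0621) or 2 (0.0553) and with limma-voom (0.138, the highest of its alternatives), PpCO2_136231 without nitrate 400 ppm replicates 1 (0.164) or 3 (0.187, its highest) or nitrate 720 ppm replicates 1 (0.134) or 2 (0.0965) with limma-voom (0.0516) and with the replicate number as a block (0.0752).

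Most of these root transcripts, though not most of their summed CPM, were hardly present in the shoot. Transcripts with a mean CPM in roots over 100 times that in needles and stem, a limit set after the data were seen, are called root-restricted. They made up 10.9% of the transcripts tested in roots, 760 of the 876 fallen ones (86.8%) and 153 of the 221 risen ones (69.2%). The 760 summed to 645.5 ± 76.6 CPM in ammonium roots at 400 ppm, 665.5 ± 83.4 CPM at 720 ppm, 959.6 ± 263.2 CPM in nitrate roots at 400 ppm and 6.29 ± 2.09 CPM at 720 ppm (SD, n = 3). The 153 summed to 152.2 ± 21.2, 155.4 ± 19.6, 92.8 ± 5.96 and 529.5 ± 209.3 CPM in the same order. All 876 fallen transcripts summed to 3200 ± 157.4, 2761 ± 166.1, 3375 ± 387.7 and 1711 ± 45 CPM, and all 221 risen ones to 632.6 ± 42.4, 748.8 ± 42.2, 483.7 ± 19.2 and 1230 ± 263.2 CPM. Of the calls, 116 fallen and 68 risen transcripts were not root-restricted. In a new fit and adjustment without root-restricted transcripts 31 calls were left, 3 higher and 28 lower. The log2 fold changes of PpCO2_54562 and PpCO2_136231 stayed at 1.76 and 1.19 there, with adjusted p of 0.0831 and 0.164.

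**Figure D4:**
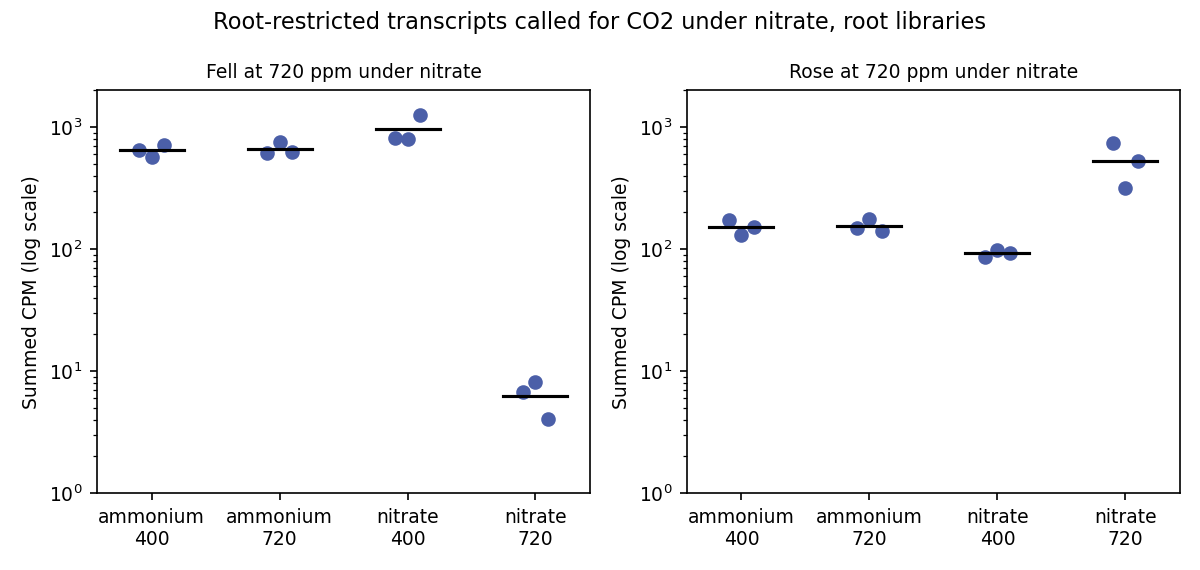
Summed CPM (vertical axis, log scale) of the 760 root-restricted transcripts that fell (left) and the 153 that rose (right) at 720 ppm under nitrate, in the 12 root libraries by group. Points are libraries and black lines group means; the fallen set lies between 645.5 and 959.6 CPM on average in 3 groups and at 6.29 CPM in nitrate roots at 720 ppm.

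The CO2 responses under ammonium and nitrate differed for 722 root transcripts by the interaction test in edgeR. The log2 fold change at 720 against 400 ppm was higher under ammonium than under nitrate for 603 and lower for 119. A higher value includes transcripts that fell under nitrate and changed little under ammonium. Of the 722, 671 were also called for CO2 under nitrate and 0 for CO2 under ammonium. PpCO2_153738 and PpCO2_25229, described above, had interaction log2 values of 10.69 (SE 0.436, edgeR adjusted p = 1.95e-07) and 9.45 (SE 0.418, edgeR adjusted p = 1.21e-06). PpCO2_67923 went from 14.9 ± 3.01 to 7.42 ± 1.07 CPM under ammonium and from 1.69 ± 0.172 to 2.96 ± 0.599 CPM under nitrate (SD, n = 3), an interaction of -1.82 on the log2 scale (SE 0.252, edgeR adjusted p = 0.00295). PpCO2_27717 went from 16.6 ± 1.53 to 8.5 ± 1.25 CPM under ammonium and from 7.08 ± 1.28 to 10.1 ± 1.2 CPM under nitrate, with an interaction of -1.48 (SE 0.209, edgeR adjusted p = 0.00332). Of the 722, 646 were root-restricted (89.5%), and 24 calls were left without those transcripts. The number with a lower log2 fold change under ammonium, 119, was 183 and 64 without ammonium 400 ppm replicates 2 and 3, 69 without ammonium 720 ppm replicate 2, 76, 61 and 56 without nitrate 400 ppm replicates 1, 2 and 3 and 68 without nitrate 720 ppm replicate 1. DESeq2 called 1946 and limma-voom 198, where PpCO2_25229 lost its call (adjusted p = 0.07, the highest of its alternatives). In needles and stem the interaction test in edgeR called 0 transcripts, with 4337 and 4234 at an unadjusted p under 0.05. DESeq2 called 46 and 63 there. Without single libraries the needle count was 2 for nitrate 400 ppm replicate 3, 3 for nitrate 720 ppm replicate 2 and 2 for nitrate 720 ppm replicate 3, and the stem count 56 for ammonium 400 ppm replicate 3 and 3 for nitrate 720 ppm replicate 2. It was 3 in needles without the low-complexity libraries, where nitrate at 400 ppm held 1 library, and 1 in stem with no low-count filter.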

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

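The tests of explanations for the 2 patterns weighed here, and the splits for 3 of the needle comparisons (CO2 under each nitrogen form, and nitrogen at 400 ppm), were chosen after the results were seen, and the other splits before.

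The CO2 response of the roots differed between ammonium and nitrate by an interaction test, for 722 transcripts. The interaction was 10.69 on the log2 scale for PpCO2_153738, 9.45 for PpCO2_25229, -1.82 for PpCO2_67923 and -1.48 for PpCO2_27717. By F-tests over all 36 libraries the CO2 response differed between organs for 130 transcripts and the nitrogen response for 1374. For the CO2 response the splits given below did not exclude chance. Its count was 13 without replicate 2 of every group and 283 with the seedling pool as a block.

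The first pattern is the 876 root transcripts that fell and the 221 that rose at 720 ppm under nitrate. Low complexity of the 3 nitrate libraries at 720 ppm was weighed with lists drawn from all tested root transcripts and matched on CPM in ammonium roots. Of their values, counted per transcript and library, 2.4% were at 0 counts there (1.64 to 4.03% over 100 lists), against 2.37% in nitrate roots at 400 ppm. These libraries thus lost transcripts of such levels about as often as those at 400 ppm, which argues against a general loss. Of the values of the fallen transcripts 75.5% were at 0 there, but these were called for low counts in the same libraries, so that share is no test. A single wrong label was excluded. For that, each of the 6 nitrate root libraries was judged by the transcripts called in a fit without it, and 6 of 6 lay beyond all libraries of the other CO2 level, on the side of their own, in the summed CPM of the fallen and of the risen transcripts. For the risen ones 2 libraries at 720 ppm were nearer the other level: replicate 2 at 480.1 CPM (other level up to 253.9, own from 794.1) and replicate 3 at 1592 CPM (up to 1232, from 2000). For the fallen ones these 2 were at 171.3 and 187 CPM, against at least 997 and 999.8 CPM at the other level. A candidate explanation is RNA of another organism living on the roots: 86.8 and 69.2% of the 2 sets were root-restricted, and between replicates 32.9% of the deviation of the fallen and 53% of that of the risen transcripts was a shift common to all members. The highest of 1000 matched lists of other root transcripts had 3.44 and 6.45%. These lists were drawn without root-restricted transcripts, so they cannot tell whether the shift is particular to the 2 sets or common to root-restricted transcripts. Pine transcripts that are regulated together in roots would give the same values. A response of the pine to CO2 under nitrate, or to a chamber or tray that went with it, therefore stays open. No sequence or name was at hand to tell them apart.

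The second pattern is the larger number of nitrogen calls in roots than in needles and stem. Low-complexity libraries of needles and stem were excluded as its whole cause, since without them the highest count there was 174, against 5545 as the lowest root count without a single library. Root-restricted transcripts were excluded as its whole cause, since 6066 calls were left at 720 ppm without them. RNA of another organism among the other transcripts could not be told apart, so it was not excluded. A larger spread between replicates in needles and stem was excluded as its whole cause, since the coefficient of variation over transcripts of at least 5 CPM was 0.151 in needles and 0.176 in stem against 0.149 in roots, at most 1.18 times as large. Among these transcripts 1750 were higher and 3466 lower with ammonium in roots at 400 ppm and 1153 and 2286 at 720 ppm, against 54 and 35, and 37 and 34, in needles and 41 and 45, and 51 and 53, in stem. A stronger response of roots to nitrogen form, or to the chloride and potassium given with it, remains a hypothesis.

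Other splits of the same libraries were counted for each result. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. For CO2 under ammonium, CO2 under nitrate, nitrogen at 400 ppm and nitrogen at 720 ppm, the real counts were 2, 8, 121 and 89 in needles, where the highest other splits gave 0, 0, 1 and 0. In stem the real counts were 0, 0, 121 and 131, and every other split gave 0. In roots they were 10, 1097, 12456 and 9653, and the highest other splits gave 1, 0, 1 and 1. The interaction was drawn 100 times on 15000 transcripts. In roots the real split gave 84 calls and the highest other 105, and 3 of 100 splits, the real one included, gave as many. That share is under 0.05 but was not adjusted over the results that were split. Labels were drawn within each nitrogen form, so other splits can keep the real CO2 labels of 1 form. Chance was therefore not called excluded in roots. In needles and stem the real split gave 0 and the highest other 1. All 100 splits give as many as 0 by construction, so chance was not weighed there. Between organs, 25 splits on 15000 transcripts were counted. The real count was above all others for needles against stem (6003 calls, highest other 1045), needles against roots (8311 and 1), stem against roots (5845 and 0) and the organ difference in the nitrogen response (138 and 3). Each had 1 split as large, the real one, a share under 0.05 that was likewise not adjusted. For the organ difference in the CO2 response chance was not excluded (1 and 3, with 2 splits as large).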

How the results depend on the processing

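The removal of low-complexity libraries, the removal of root-restricted transcripts and limma-voom with library weights were chosen after the data were seen. No root library was of low complexity, so that first alternative was not run for roots. Of 39 results for named transcripts, 12 kept their call under every alternative, 27 lost it under at least 1 and 0 reversed. Where a count moved by over 1.5 times, the cause was not tested, except that a higher fold or stricter p threshold calls fewer transcripts by construction.

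Counts of calls are given for CO2 under ammonium, CO2 under nitrate, nitrogen at 400 ppm, nitrogen at 720 ppm and the interaction where they moved. A fold change over 2 left 0 and 3 for CO2 in needles, and 3 (CO2 under ammonium), 7099 and 6425 (nitrogen) in roots. An adjusted p under 0.01 left 11 transcripts for the organ difference in the CO2 response and 673 for nitrogen. DESeq2's size factors gave 3 for CO2 under nitrate in needles, 2 for CO2 under ammonium in stem and 75 for the organ difference in the CO2 response. With no low-count filter the needle counts were 168, 329, 250 and 182, those of stem 12 (CO2 under ammonium) and 1 (interaction), and that of CO2 under ammonium in roots 36. DESeq2 called 1042, 950, 1158, 550 and 46 in needles, 494, 189, 538, 820 and 63 in stem and 1150, 2831, 20638, 16252 and 1946 in roots. limma-voom called 146, 188, 41 and 551 in needles, 3 (CO2 under nitrate), 49 and 340 (nitrogen) in stem, and 75 (CO2 under ammonium), 14854 (nitrogen at 720 ppm) and 198 (interaction) in roots. Without low-complexity libraries the counts were 20, 35, 174 (nitrogen at 720 ppm) and 3 (interaction) in needles, 8 (CO2 under ammonium) and 65 (nitrogen at 400 ppm) in stem and 75 for the organ difference in the CO2 response. Without root-restricted transcripts they were 31 (CO2 under nitrate), 6066 (nitrogen at 720 ppm) and 24 (interaction) in roots. Of 45 list tests 8 passed, 0 with an estimated correlation and 16 with lists at a log2 fold change over 1, where 2 passed with an estimated correlation (adjusted p = 0.0392 and 0.0415).

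With the replicate number as a block, CO2 gave 19 and 173 calls in needles and 105 under ammonium in roots, 63 of them higher, and nitrogen at 720 ppm in needles 59 higher and 51 lower. Under nitrate in roots, where the numbers were taken to pair the libraries by their correlations and not by the labels, it gave 1107 against 1097. With the seedling pool as a block the organ difference in the CO2 response had 283 calls. No other count moved by over 1.5 times with a block.

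Without single libraries the counts ran, in the order above, from 0 to 4, 0 to 89, 43 to 157, 44 to 80 and 0 to 3 in needles, from 0 to 298, 0 to 3, 64 to 558, 49 to 61 and 0 to 56 in stem, and from 0 to 4, 674 to 794, 6268 to 9622, 5545 to 8013 and 504 to 800 in roots. Without each replicate number they ran from 55127 to 69964 for needles against stem, 84348 to 95959 for needles against roots, 56035 to 64406 for stem against roots, 13 to 187 for the organ difference in the CO2 response and 221 to 940 for that in the nitrogen response. Depth limits what a count of 0 shows: 3 counts over a root group correspond to 0.0104 to 0.0121 CPM, and 3 independent fragments, as estimated from transcripts near 1 CPM, to 0.189 to 0.226 CPM.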

Other observations

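Root-restricted transcripts differed in the root groups in which they were present, a description chosen after the data were seen. Of 4234 with at least 0.5 CPM, 3430 were above 5% of their highest group in all 4 groups. Another 325 were absent by that measure in nitrate roots at 720 ppm alone, where they summed to 4.34 ± 1.47 CPM against 741 ± 206 CPM in nitrate roots at 400 ppm (SD, n = 3). For 163 transcripts only ammonium roots at 400 ppm lacked them, with 14.4 ± 8.78 CPM. They were at 71.4 ± 37.8 CPM in ammonium roots at 720 ppm, also far below the 685 ± 374 and 643 ± 69.2 CPM in nitrate roots at 400 and 720 ppm. Both ammonium groups lacked 118, at 4.83 ± 1.87 and 7.45 ± 5.47 CPM, against 298 ± 160 and 309 ± 47.2 CPM with nitrate. Present in ammonium roots at 400 ppm and nitrate roots at 720 ppm alone were 62, at 21.9 ± 16.4 and 269 ± 150 CPM. Only nitrate roots at 400 ppm lacked 45, at 2.29 ± 0.859 CPM against 53.2 ± 20 CPM in nitrate roots at 720 ppm, and only ammonium roots at 720 ppm lacked 35, at 2.24 ± 0.814 CPM against 16.8 ± 8.3 CPM in ammonium roots at 400 ppm. Another 30 were present in nitrate roots at 720 ppm alone, at 109 ± 60 CPM, and 26 showed other combinations. The transcripts were sorted by the same group means that were then summed, so low sums follow from the sorting and are no test. For transcripts near 0.5 CPM, 5% of the highest group lies below the level of 3 independent fragments, so absence is uncertain there.

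All root-restricted transcripts together took 1.85 ± 0.114% of the counts in ammonium roots and 3.02 ± 0.239% in nitrate roots (SD, n = 6, two-sided exact permutation p = 0.00216, the smallest possible). By CO2 the shares were 2.54 ± 0.707% at 720 ppm and 2.33 ± 0.61% at 400 ppm (exact p = 0.563). Needle and stem libraries held 0.00251 to 0.0161%.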
